A study of Homo sapiens with 8 samples.

How the data were processed

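Cultures of MDA-MB-435 from primary tumours and from lung nodules of 2 mice were profiled on 8 arrays, 2 per mouse and site. Total RNA was isolated with a miRNA isolation kit and labelled with Cy3 by the standard Agilent protocol, per the labels' protocols. The scanner files hold spot intensities from Agilent Feature Extraction 10.7.3.1, per the file headers. In the deposited files the processed intensity of a spot is background-subtracted, is not scaled between arrays and can be negative. A deposited value table of the series holds log2 values that appear largely quantile-normalized from the total signal per miRNA, with undetected miRNAs at a lowest value shared within each array. The highest value of the table was 13.80 on each array except replicate 2 of the lung nodule culture of mouse 1 (14.21). Full quantile normalization would give every array the same highest value. Its normalization method is not given in the sources used here, and the median of each column equals that lowest value: -3.32, -3.24 (primary tumour, mouse 1, replicates 1 and 2), -3.26, -3.30 (lung nodule, mouse 1), -3.29, -3.32 (primary tumour, mouse 2) and -3.28, -3.20 (lung nodule, mouse 2). Its log2 scale and direction were checked against the scanner values, with correlations of 0.973 to 0.999 per array. The detection, outlier and saturation flags were taken as deposited.

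For each array, control spots and spots flagged as outliers (6.03% to 7.69% of spots) were left out. Processed signals were averaged over the spots of a probe and then over the probes of a miRNA. Most miRNAs had 2 (498) or 4 (378) probes. Each value was divided by the array's 75th percentile over the 203 human miRNAs detected on all 8 arrays, which lay between 154 and 219 signal units. Values were then floored at 0.0103, the median over arrays of percentile 1 of detected miRNAs, and log2-transformed (floor -6.60). The tested set was the 269 human miRNAs that Feature Extraction called detected on at least 2 arrays. Viral miRNAs were not tested. Where a miRNA was undetected on all arrays of a site, a bound was formed from the bright site's mean. It was set against the mean of, per array, the higher of the lowest detected signal and the miRNA's own value. That lowest signal was taken after flooring, so it equals the floor by construction. The bound thus equals the fitted fold and rests on the chosen floor, not on a measured detection limit. It is written as at least N-fold only where all arrays of the dim site lay at the floor, and elsewhere the fitted log2 difference is given, with a dim site not well above background. miRNAs keep the names of the array design, with no translation between database versions. A RefSeq gene table of GRCh38.p14, used only for names and for which genes neighbour each other, matched 247 of the 269 names. The file headers name another build, so no coordinates are given.

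Differences were tested with limma 3.58.1 in R 4.3.3, with a variance trend and Benjamini-Hochberg adjustment at 0.05. The comparison of sites over both mice used all 8 arrays with mouse as a term (5 residual degrees of freedom). The difference within each mouse and the difference between mice came from a model of 4 group means (4 residual degrees of freedom). Both slides held both sites, each slide held a single mouse, and positions on the slide were split by site in the same way on both, so slide cannot be told apart from mouse nor position from site. The slide as a block is the same fit as the mouse term. miRNA lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which asks whether the members themselves changed and does not compare them with other miRNAs. Figures and permutations used Python 3.11.15.

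Named miRNAs followed a rule. Of those past the threshold with the same sign in both mice, the 12 largest rises and the 12 largest falls were named. The rule also took the 6 largest rises and falls of each mouse, those that pass in the difference between mice, miR-374a and miR-374b with their opposite arms, and up to 4 members of each list. Other list members with values were chosen after their values were seen. Lists were matched by hairpin name, so both arms of a hairpin counted as members, whichever arm a list's description refers to. The rule, the lists, the tests of the comparisons and lists and the alternatives were fixed before the data were examined. Keeping outlier-flagged spots was added later, as were the tests said below to be chosen after the result was seen. Alternatives covered the percentile over all human miRNAs, quantile normalization, no scaling, median scaling, normexp with an offset of 50, the total signal per miRNA, the brightest probe, other floors, other filters, the deposited value table, no variance trend, averaged replicates, culture as a random block, other block designs and leaving out each array. Normexp used median spot signals, because the files have no mean spot signal column.

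On simulated data with 60 of 269 miRNAs changed (20 simulations), the comparison over both mice recovered 46.0% of changes of 0.25 on the log2 scale, 75.0% at 0.50, 94.3% at 1.00 and 100% at 2.00, with 3.47% false calls. The comparison within mouse 1 recovered 24.0%, 56.0%, 85.0% and 98.0%, with 4.71% false calls. For the difference between mice, simulated with no effect, 2 calls were made in 20 simulations. Simulated miRNAs vary independently, which real ones need not. The simulation also had no floor and no spread between mice or cultures beyond that between arrays, so these rates hold only under those conditions.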

Results

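MicroRNA signals were measured in cultures of MDA-MB-435, a human cancer cell line that the labels describe as breast cancer and that later genotyping work assigned to the melanoma lineage. The cells had grown as tumours in the mammary fat pads of nude mice. After 30 days, cultures were started from the primary tumour (labelled parental) and from lung nodules (labelled metastasis) of the same animals, per the sample labels. The series design text instead calls the control group parental cells, and the sample labels were followed here. Each of 2 mice gave both kinds of culture, and each mouse and site was measured on 2 arrays, 8 arrays in all. The series title names miR-374a, epithelial-mesenchymal transition and metastasis, so the question was which miRNAs differed between cells recovered from the lung and cells recovered from the primary tumour.

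Every 1-colour array carried probes for 851 human and 88 viral miRNAs, with 16 spots for each. Between 225 and 264 human miRNAs per array were called detected. Of these, 203 were detected on all 8 arrays, and the 269 detected on at least 2 arrays were tested. No spot was saturated (0 on every array), and negative control spots averaged between 1.84 and 3.16 signal units. The 5 brightest miRNAs took 41.1% to 42.7% of the human miRNA signal on primary tumour arrays and 54.1% to 57.1% on lung nodule arrays. Replicate arrays were close, with Pearson correlations across the 203 miRNAs of 0.994 to 0.998. The SD of the log2 difference between replicates had a median of 0.21, against 0.25 between mice at the same site and 0.82 between sites in the same mouse. The series design text speaks of 2 biological replications, while the sample labels do not say whether the 2 replicates per mouse and site were separate cultures, so p-values here measure only the spread between these arrays, which may be technical. The small number of arrays limits the precision.

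miR-374a had the largest rise in the lung nodule cultures among miRNAs detected on all 8 arrays. Its mean signal was 76.0 units in primary tumour cultures and 10675 in lung nodule cultures (n = 4 arrays each). The log2 difference was 7.37 ± 0.09 (SE), or 165-fold, with an adjusted p of 1.75e-11 in limma with Benjamini-Hochberg adjustment. The difference was 7.42 in mouse 1 and 7.32 in mouse 2, and both of its probes rose. The related miR-374b, which can share signal with miR-374a through sequence similarity, had a log2 difference of 0.10 ± 0.09 and did not pass (limma adjusted p = 0.372). The rise of miR-374a thus did not visibly carry over to the miR-374b probes. The opposite hairpin arms miR-374a* and miR-374b* were detected on 0 arrays and were not tested.

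In the same comparison 65 of the 269 tested miRNAs rose and 78 fell in lung nodule cultures, all of them with the same sign in both mice. A change of at least 2-fold was fitted for 13 of the rises and 19 of the falls (4 and 4 with normexp, 7 and 23 without scaling, 22 and 25 in the deposited value table). After miR-374a, miR-330-3p rose by 7.25 ± 0.10 on the log2 scale, from a mean signal of 1.23 to 306 units. It was detected on 0 of 4 primary tumour arrays and on 4 of 4 lung nodule arrays. Likewise miR-26a-1*, at least 23.5-fold higher at the floor used, and miR-302a, a member of a pluripotency-associated cluster, 3.85 ± 0.12 higher, were detected on lung nodule arrays only. The opposite arm of miR-302a and its cluster neighbours miR-302b, miR-302c, miR-302d and miR-367 were detected on 0 arrays. miR-489 rose by 3.94 ± 0.10, from 16.1 to 208 units. miR-630 rose by 2.56 ± 0.23 and was detected on 1 of 4 primary tumour arrays. Because these primary tumour levels lie near background, the log2 values depend on background handling. Across the scalings tried they ranged from 2.71 to 11.84 for miR-330-3p, from 0.88 to 8.91 for miR-26a-1*, from 0.70 to 8.44 for miR-302a, from 1.99 to 3.98 for miR-489 and from 0.37 to 6.91 for miR-630, always past the threshold as rises.

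The next rises were smaller. miR-21*, from the hairpin of the widely studied oncogenic miR-21, rose by 1.39 ± 0.07 and miR-25 by 1.19 ± 0.06. miR-421 rose by 1.18 ± 0.13, miR-1275 by 1.08 ± 0.07, miR-1260 by 1.05 ± 0.10 and miR-652 by 1.03 ± 0.06. Their lowest values over the scalings were 0.74 for miR-21*, 0.95 for miR-25, 0.32 for miR-421, 0.54 for miR-1275, 0.81 for miR-1260 and 0.49 for miR-652. The deepest falls were of miR-196a, encoded in the HOX gene clusters, at -2.89 ± 0.13, and of both arms of the miR-30a hairpin, miR-30a* at -2.56 ± 0.11 and miR-30a at -2.23 ± 0.04. miR-34a, a p53 target with tumour-suppressive activity, fell by 1.82 ± 0.05, to 122 signal units. miR-27b fell by 1.48 ± 0.05, miR-34b* by 1.44 ± 0.09 and miR-497 by 1.41 ± 0.09. The smallest falls over the scalings were -0.47 for miR-196a, -0.48 for miR-30a*, -1.43 for miR-30a, -1.46 for miR-34a, -1.36 for miR-27b, -0.11 for miR-34b* and -0.21 for miR-497. A further set was detected on all 4 primary tumour arrays and on 0 lung nodule arrays. At the floor used, it held miR-218, at least 3.07-fold lower, and miR-34a*, at least 2.59-fold lower. Lung nodule values above the floor, though not well above background, gave log2 differences of -2.09 ± 0.20 for miR-574-3p, -1.59 ± 0.11 for miR-95 and -1.52 ± 0.23 for miR-24-1*. In mouse 2 miR-574-3p fell by 1.59 and miR-24-1* by 1.04. With normexp background correction, miR-218, miR-95, miR-24-1* and miR-34a* turned to values of 0.03, 0.05, 0.01 and 0.04.

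**Figure D1:**
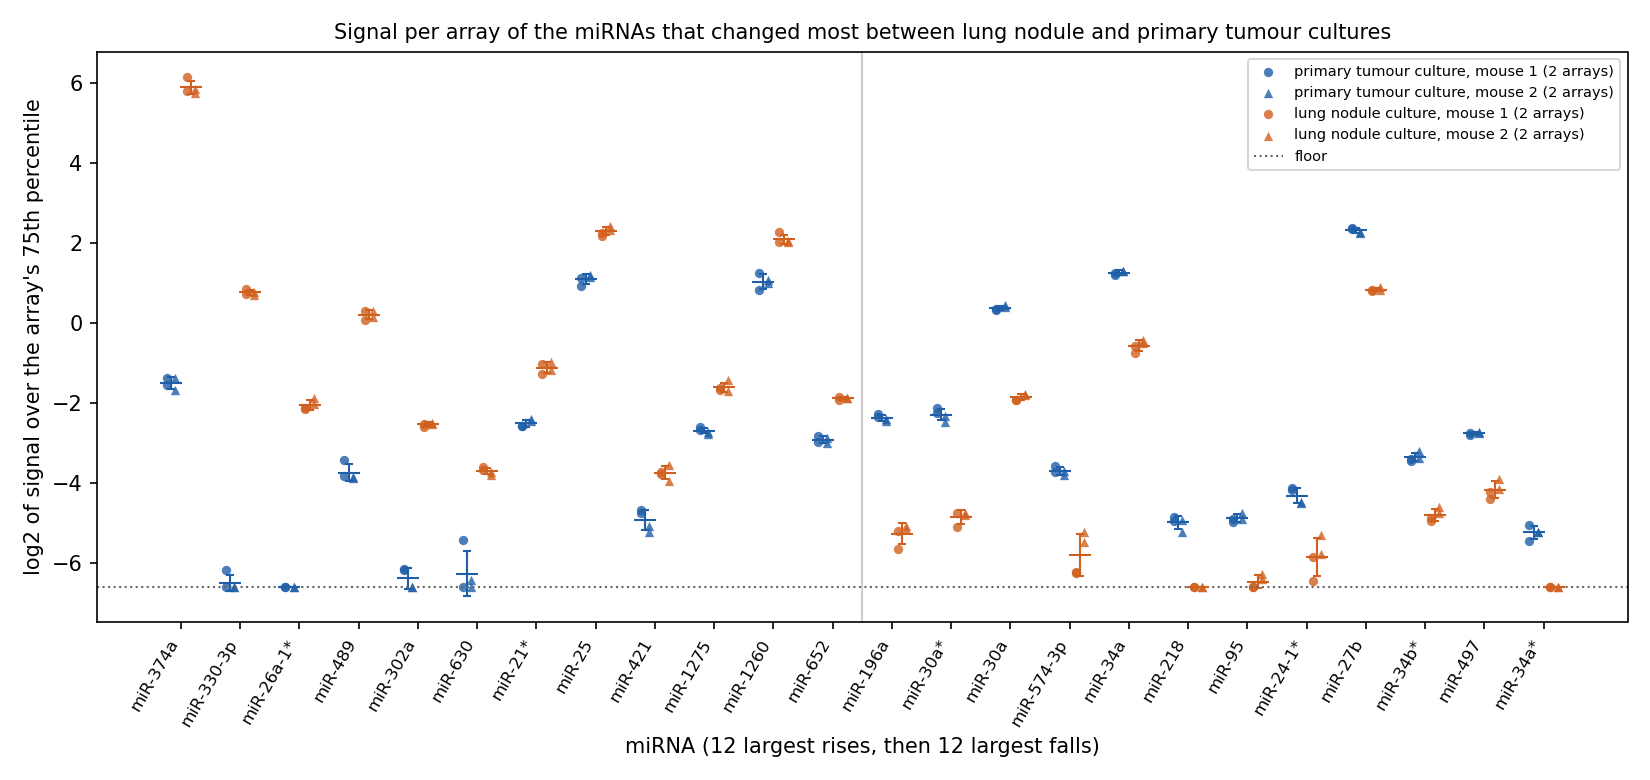
Each point is the signal of a miRNA on an array, as log2 of the signal over the array's 75th percentile. Blue marks primary tumour cultures, orange lung nodule cultures, circles mouse 1 and triangles mouse 2, bars give the mean and SD over the 4 arrays of a site, and the dotted line is the floor at -6.60.

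The balance of rises and falls depended on the scaling. The fitted split was 65 rises to 78 falls, with a median log2 difference of 0.05 over all tested miRNAs. It was 80 to 62 with the percentile taken over all human miRNAs, 41 to 109 without scaling (median -0.19), 46 to 110 with median scaling (median -0.15) and 44 falls among 147 changed miRNAs (70.1% rises) with normexp (median 0.13). Changes below are relative to the 75th percentile of the 203 miRNAs. Of the miRNAs that passed, 66 (35 rises and 31 falls) kept their direction and their call under all 8 other ways of scaling or summarising, and 35 changed sign under at least 1 of them. Leaving out replicate 1 of the primary tumour culture of mouse 1 gave 94 rises and 74 falls.

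The miR-15/16 family, whose members target cell cycle genes, was lower in lung nodule cultures. Of 9 tested members 0 rose, 8 fell and 1 did not pass, with the same counts when adjusted over the list alone. The number of falls was 7 in each mouse alone, 7 with quantile normalization, 9 without scaling and 6 with replicates averaged, with 0 rises in each. miR-497 and miR-195 (-1.37 ± 0.07) come from a shared cluster. miR-424 fell by 0.82 ± 0.06, and miR-15b fell from 1566 to 882 signal units, by 0.59 ± 0.06. Of the members that fell, miR-503 and miR-16-2* reached 0.03 and 0.11 under 1 scaling. This was the only list of 17 to pass camera with a preset correlation of 0.01 (adjusted p = 0.00391). The call was lost with an estimated correlation (adjusted p = 0.565).

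Members of the miR-23a and miR-23b clusters changed in opposite directions. All 7 tested members of the miR-23/24/27 list changed, 2 up and 5 down. From the miR-23b cluster, miR-23b fell by 1.28 ± 0.05, miR-27b fell as given above, and miR-24-1* and miR-23b* (-0.81 ± 0.13) fell from dim levels to none detected. The paralogous miR-23a and miR-27a rose by 0.60 ± 0.05 and 0.63 ± 0.05. miR-24, encoded in both clusters, fell by 0.37 ± 0.05. With normexp, miR-23b* and miR-24-1* were at 0.10 and 0.01. The miR-17-92 cluster and its paralogs split in a similar way, with 5 rises, 9 falls and 5 members that did not pass among 19 tested. The rises were of the miR-106b/25 cluster, with miR-25 as above, miR-106b at 1.01 ± 0.05, miR-93 at 0.98 ± 0.04 and both of their passenger arms, miR-106b* and miR-93*. The miR-106b* call did not pass in mouse 1, and that of miR-93* (0.49 ± 0.18) passed in neither mouse alone and in 4 of 8 scalings. The falls included miR-19a (-0.68 ± 0.08), miR-19b (-0.59 ± 0.06), miR-20a (-0.47 ± 0.06) and miR-17 (-0.38 ± 0.05). Within this list miR-17* and miR-18b, which fell, reached 0.06 and 0.06 under 1 scaling. Without scaling 4 rose and 10 fell in the miR-17-92 list. Neither list passed camera (adjusted p = 0.245 and 0.698), and counts adjusted over each list alone were unchanged.

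Of 8 tested members of the miR-30 family 2 rose and 6 fell. Besides miR-30a and miR-30a*, miR-30e* fell by 1.08 ± 0.10 and miR-30c by 0.87 ± 0.05, while miR-30d rose by 0.46 ± 0.05 and miR-30b by 0.38 ± 0.05. miR-30c-2*, which fell at least 1.78-fold to no detection at the floor used, reached 0.09 under 1 scaling. Among 13 tested arms of let-7 family hairpins, a family known for restraining growth-related targets, 2 rose, 6 fell and 5 did not pass. Adjusted over the list alone, 3 rose and 6 fell. let-7b fell by 0.75 ± 0.08, let-7a by 0.37 ± 0.06 and let-7c by 0.32 ± 0.06, and let-7f-1* was 0.43 ± 0.14 higher. The let-7f-1* call was lost in 9 alternatives and passed in neither mouse alone, and with replicates averaged 0 members of the list rose. miR-98, the other rise, reached -0.07 under 1 scaling. In the miR-29 family, whose targets include collagens, 3 of 5 rose and 1 fell. miR-29a rose by 0.76 ± 0.07, miR-29b by 0.27 ± 0.05 and miR-29b-1* by 0.77 ± 0.18, detected on 0 of 4 primary tumour and 3 of 4 lung nodule arrays and not past the threshold in mouse 1 (0.35) or in 4 alternatives, and miR-29c fell by 0.46 ± 0.06. Without scaling the counts were 0 rises and 6 falls for miR-30, 0 and 8 for let-7 and 2 and 2 for miR-29. Adjusted over each list alone, miR-30 and miR-29 kept their counts. Camera adjusted p-values were 0.0729 for miR-30, 0.341 for let-7 and 0.649 for miR-29.

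The miR-200 family with miR-205, which maintains the epithelial state, was detected in both kinds of culture. All 10 members were tested, of which 0 rose, 4 fell and 6 did not pass, with the same counts when adjusted over the list alone. miR-200b fell by 0.49 ± 0.07, to 255 signal units, and miR-429 by 0.25 ± 0.06. miR-200a* (-0.61 ± 0.17, undetected on lung nodule arrays) and miR-205 (-0.60 ± 0.08) also fell, but stood at 0.12 and 0.01 with normexp. The bright members miR-200c and miR-141 differed by -0.04 ± 0.06 and 0.04 ± 0.06. The number of falls was 7 without scaling, and 1 member rose with quantile normalization. The list did not pass camera (adjusted p = 0.265).

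Of the 6 tested p53-responsive miRNAs 0 rose and 3 fell, all of the miR-34 family (miR-34a, miR-34a* and miR-34b*), and camera gave an adjusted p of 0.0729. Among 6 tested arms of miRNAs reported to promote metastasis 2 rose, both from the miR-21 hairpin, and 2 fell. miR-21, the brightest miRNA on every array, rose by 0.85 ± 0.09 and miR-21* rose as above, while miR-9 (-0.62 ± 0.13) and miR-107 (-0.14 ± 0.04) fell. The miR-107 call was lost in 5 alternatives, averaged replicates among them, and passed in neither mouse alone. The miR-21 difference was 0.00 after quantile normalization, which gives the brightest miRNA of each array the same value, and miR-9 was 0.11 with normexp. Among 6 tested arms of miRNAs reported to suppress metastasis 1 rose, miR-193b by 0.44 ± 0.04. Another 3 fell, miR-126 and both arms of the miR-34a hairpin, miR-34a and miR-34a*. Adjusted over each list alone these counts were the same, and camera adjusted p-values were 0.910 and 0.341. In the list named for miR-374 and miR-421 2 of 3 tested members rose, miR-374a and miR-421, and miR-374b did not pass (camera adjusted p = 0.0729). Within 10 kb miR-421 neighbours miR-374b and not miR-374a, so the 2 rises are not of neighbouring genes. Of 6 tested members of the family of miR-99, miR-100 and miR-125 1 fell, miR-125a-5p at -0.64 ± 0.06, and of 4 in the cluster of miR-183, miR-96 and miR-182 1 fell, miR-96 at -0.27 ± 0.06. Their camera adjusted p-values were 0.649 and 0.649, and counts adjusted over each list alone were again the same. The hypoxia-induced miR-210 fell by 0.51 ± 0.08.

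**Figure D2:**
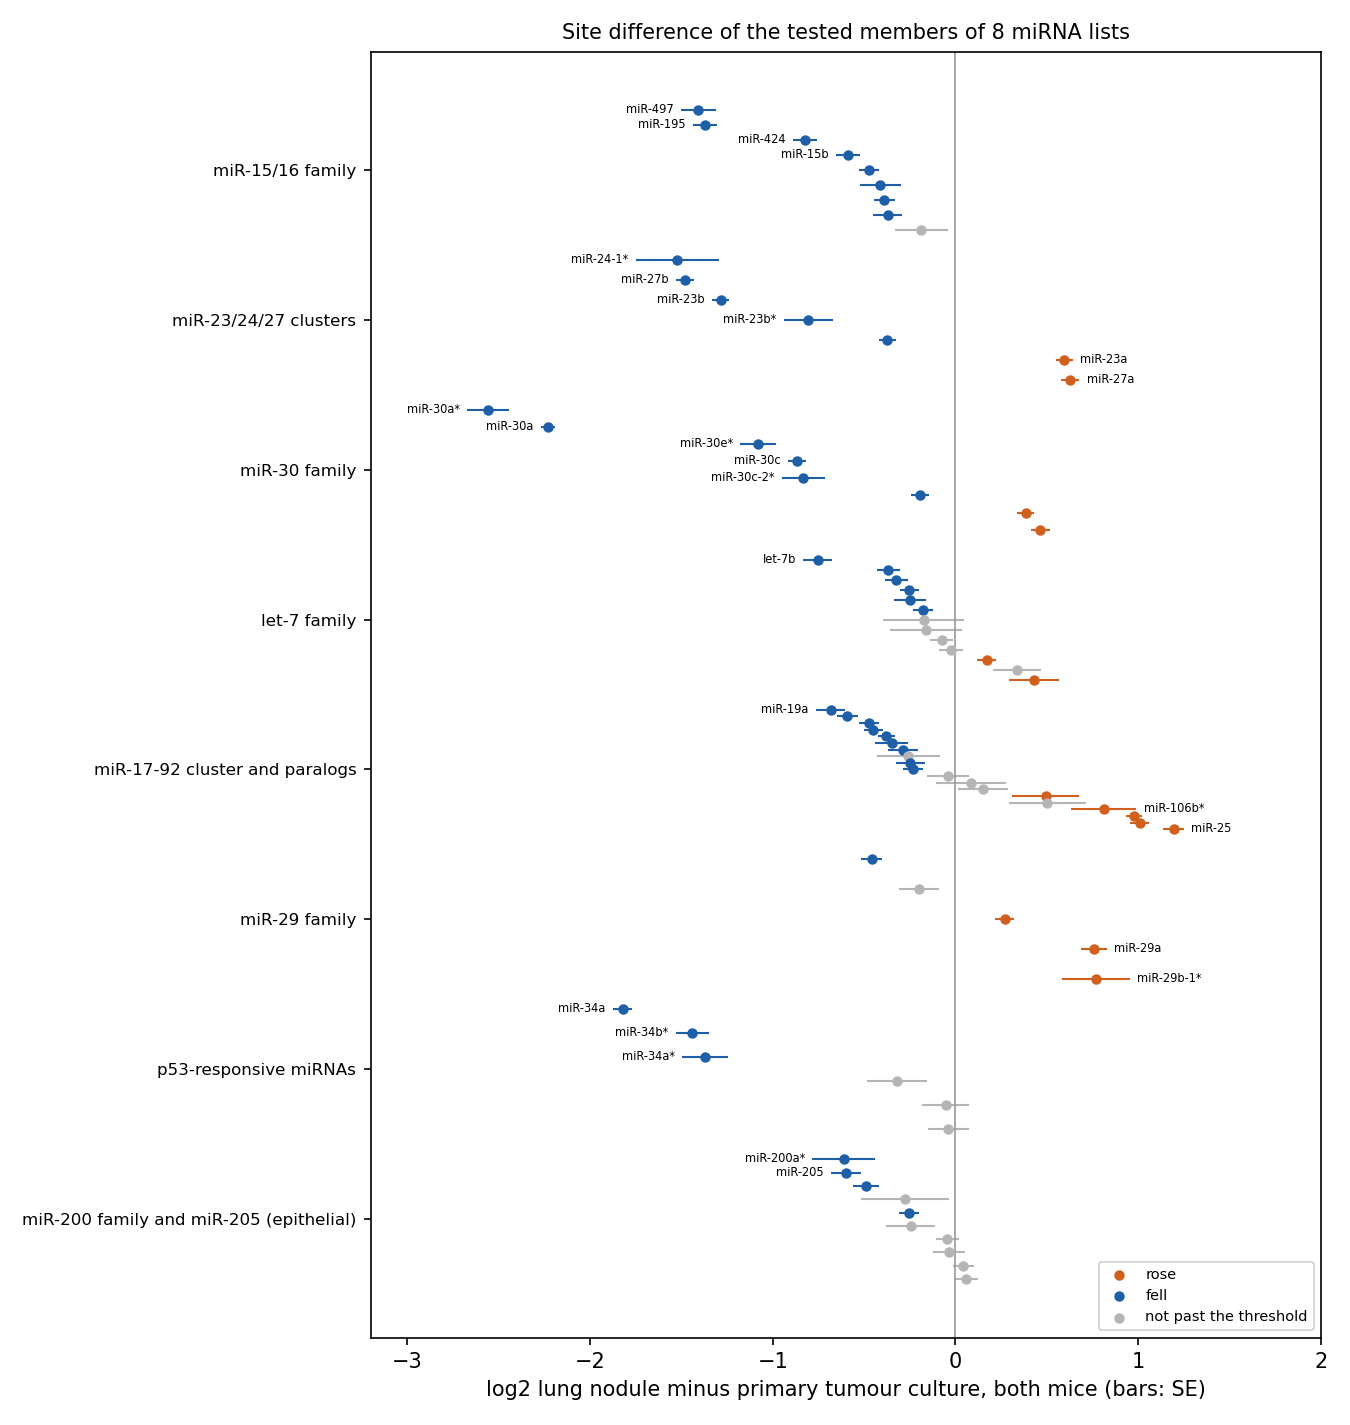
Points are log2 differences between lung nodule and primary tumour cultures in the fit of both mice, with bars of 1 SE, for the tested members of 8 lists (orange rose, blue fell, grey did not pass). miR-23a and miR-27a lie near 0.60 while miR-23b and miR-27b lie at -1.28 and -1.48, and 8 of 9 members of the miR-15/16 family lie on the negative side past the threshold, although miR-503 and miR-16-2* reached 0.03 and 0.11 under 1 scaling.

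Lists of other cell types were mostly below detection. Of 9 miRNAs of fibroblasts and smooth muscle on the array, 9 were detected on no array, as were 8 of 11 of blood cells, 5 of 6 of ciliated airway epithelium, 43 of 43 from the chromosome 19 cluster and 61 of 64 from the imprinted 14q32 cluster. The blood cell miRNA miR-223 had a difference of 0.33 ± 0.15 and did not pass, but passed as a rise with the percentile over all human miRNAs (0.36) and with normexp (0.17). The endothelial miR-126 fell by 0.29 ± 0.09, though it was at 0.08 with normexp, and its call was lost in 6 alternatives. miR-494 of 14q32 was 0.63 ± 0.21 lower, a call lost in 13 alternatives and passed in neither mouse alone. Of 15 miRNAs of the melanocyte lineage and Xq27 cluster 12 were detected on no array and 0 of 3 tested passed, with miR-513a-5p at 0.05 ± 0.25. Without replicate 1 of the primary tumour culture of mouse 1, miR-513b (0.32) and miR-513c (0.43) passed as rises. For miR-221 and miR-222, 3 of 4 arms were detected on no array and 0 were tested. Camera adjusted p-values were 0.910 for the melanocyte list and 0.910 for 14q32.

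Some members of 2 lists tied to RNA quality rose in lung nodule cultures. Among 10 tested names known to capture fragments of other RNAs, 5 rose and 0 fell, with miR-1260 as above, miR-1274a at 0.94 ± 0.05, miR-1280 at 0.67 ± 0.08 and miR-720 at 0.50 ± 0.09. miR-720 was at -0.47 after quantile normalization, under which 3 of these rose and 2 fell. Among 15 tested GC-rich miRNAs prone to background, 5 rose and 0 fell, with miR-630 and miR-1275 as above, miR-575 at 0.64 ± 0.19 (lost in 8 alternatives) and miR-1268 at 0.50 ± 0.10. The number of rises in this list was 2 without scaling, 2 in mouse 1 and 5 in mouse 2. Adjusted over each list alone both counts were the same, and camera adjusted p-values were 0.135 and 0.0729. The members that rose did so in the contrast that gave the other changes between the sites.

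Many of the same miRNAs changed within each mouse. In mouse 1, 47 miRNAs rose and 67 fell (114), and in mouse 2, 66 rose and 53 fell (119). At the floor used, the same 6 miRNAs rose most in both mice, from miR-374a and miR-330-3p to miR-630. The order of the falls also rests on the floor, since miR-574-3p, miR-24-1* and miR-218 were undetected on all lung nodule arrays, and miR-24-1* and miR-218 were at 0.01 and 0.03 with normexp. In mouse 1 the deepest fitted falls were miR-196a (-3.10), miR-30a* (-2.74), miR-574-3p (-2.58), miR-30a (-2.25), miR-24-1* (-2.0) and miR-34a (-1.89). In mouse 2 they were miR-196a (-2.67), miR-30a* (-2.38), miR-30a (-2.21), miR-34a (-1.75), miR-574-3p (-1.59) and miR-218 (-1.53). A total of 46 miRNAs rose in both mice and 50 fell in both, against 11.5 and 13.2 for independent lists, and 0 changed in opposite directions. The lists of the 2 mice share a spread estimated over all arrays, so they are not fully independent. Across the 269 miRNAs, which are not independent replicates, the differences of the 2 mice correlated with r = 0.967 and rho = 0.889. Without the 6 largest rises r was 0.918. Each mouse was hybridised on a slide of its own, so these are also the values within each slide. The splits moved with scaling here too, to 56 and 36 in mouse 1 and 44 and 54 in mouse 2 with the percentile over all human miRNAs, to 27 and 80 and to 25 and 87 without scaling, to 39 and 94 and to 41 and 100 with median scaling. In mouse 2 they were 49 and 72 with quantile normalization, 46 and 67 in the deposited value table and 78 and 35 with normexp, which called 75 in mouse 1.

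**Figure D3:**
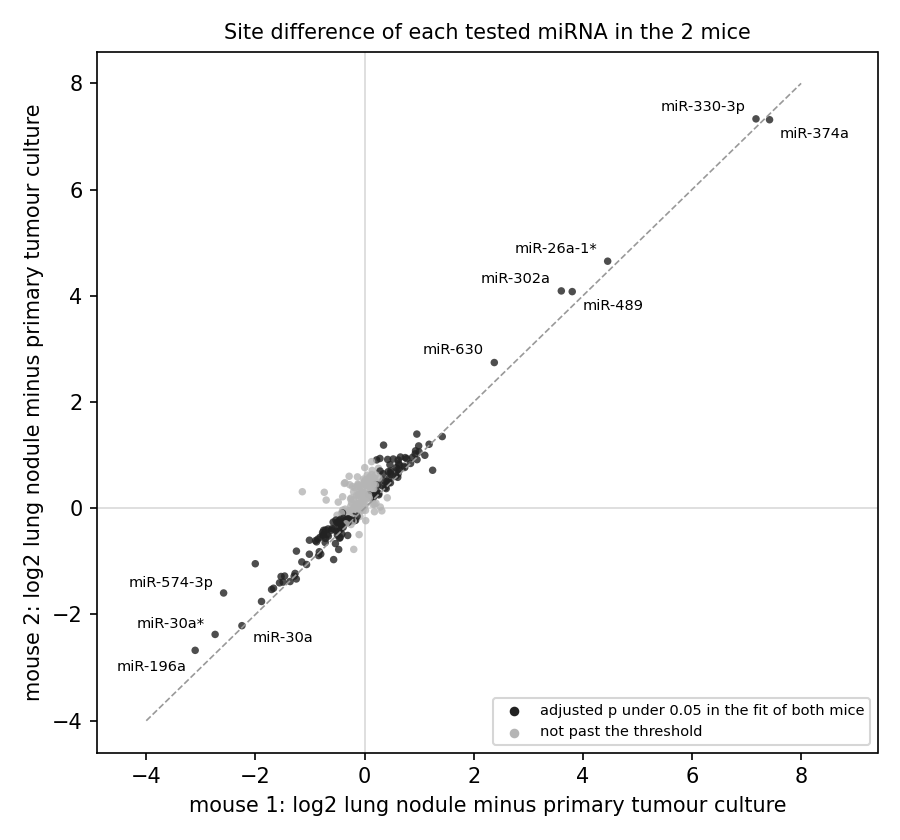
Each point is a tested miRNA, with its log2 difference between lung nodule and primary tumour cultures in mouse 1 on the horizontal axis and in mouse 2 on the vertical axis. Black points passed in the fit of both mice, grey points did not, and the dashed line marks equal values.

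The site difference itself was not shown to differ between the mice for any miRNA. In limma's interaction contrast 0 of 269 passed after Benjamini-Hochberg adjustment, with 12 at an unadjusted p under 0.05. The difference for miR-374a was 0.11 ± 0.20 lower in mouse 2 than in mouse 1 (log2 -0.11). The count was 2 with quantile normalization, 3 with normexp and 1 with a lower floor, 2 without replicate 2 of the primary tumour culture of mouse 1 and 1 without replicate 1 of the lung nodule culture of mouse 1.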

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

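The test of other splits of the arrays was fixed before the data were examined, and the tests of spots, partner miRNAs and host cells were chosen only after the result was seen. The 35 ways to split the 8 arrays into 4 and 4 were each fitted in limma without a mouse term. Only 1 split, the real one, gave as many as its 133 calls, and the highest of the others gave 0. The other splits mix the sites, so the site difference enters their spread and favours few calls. Their 0 calls therefore do not exclude chance, and the share of 1 in 35 holds only if the 8 arrays are independent samples. Only 3 of these splits keep the 2 arrays of each mouse and site together, too few for a share under 0.05 if the arrays are not independent.

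A set of 6 miRNAs rose over 4-fold in lung nodule cultures, from miR-374a to miR-630. Uneven or damaged spots are argued against, since the highest CV over the spots of a probe on any lung nodule array was 26.5%, and all 14 probes rose, the least by 1.75 on the log2 scale. RNA of stromal, blood or endothelial cells of the host is also argued against in the main fit. Of the 22 listed miRNAs 0 rose past the threshold and 18 were detected on no array. Of the 2 tested, miR-126 fell by 0.29 and miR-223 stood at 0.33 ± 0.15 without passing in limma. miR-223 passed in 2 alternatives, at 0.36 and 0.17. The rises also shrank under some scalings, with a lowest value of 0.37 for miR-630. Joint transcription with the other arm or neighbouring miRNA genes was not seen in partner miRNAs within 10 kb, but is not excluded. Of 15 partners 13 were detected on no array, where a rise below background would not show. On lung nodule arrays miR-374a averaged 10675 units, while its partners miR-374a* and miR-545 averaged -0.37 and 0.83. The 1 partner detected on all 8 arrays, miR-26a, fell by 0.50 but is also encoded at another locus. A change in the cells that grew in the lung is a candidate explanation that the design names and these tests leave untested, as are cells of host types outside the lists.

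In sets of 4 arrays of a site, 7 of 55 sets had an array set apart from the others, where chance gives 2.75. That rate does not hold for sets with arrays tied at the floor, and without them 5 of 51 sets stood apart, against 2.55. The sets of a site reuse the same 4 arrays and so are not independent, and neither count shows an excess over chance. Replicate 1 of the primary tumour culture of mouse 1 stood highest for miR-330-3p (-6.18, with the other 3 at the floor of -6.60), miR-489 (-3.43, next -3.81) and miR-630 (-5.43, next -6.42), and for the share of signal in the 5 brightest miRNAs (42.7%, next 41.2%). Replicate 1 of the lung nodule culture of mouse 1 was highest for miR-1260 (2.26, next 2.05) and lowest for miR-30a* (-5.10, next -4.79). Replicate 2 of the lung nodule culture of mouse 2 was highest for miR-27b (0.90, next 0.81). All 6 of these miRNAs differed between the sites by far more than these gaps.

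Among the viral miRNAs, which were in no comparison, 4 were called detected on all 8 arrays. The brightest, ebv-miR-BART13, had a mean signal of 71.5 ± 6.34 (SD, n = 4) in primary tumour cultures and 39.7 ± 4.43 in lung nodule cultures. Each array had 4 or 5 viral miRNAs detected of 88, and none of these signals was tested or explained.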

How the results depend on the processing

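The number of miRNAs past the threshold over both mice stayed between 115 and 156 in 19 alternatives (65 rises and 78 falls as reported) and between 124 and 168 when single arrays were left out. It was 117 with replicates averaged before the fit, of which 115 were shared with the same direction, and 133 without the mouse term. The averaged fit has only a value per mouse and site, so its p-values rest almost wholly on a spread pooled over miRNAs. Its count does not show that the result holds if the replicates are technical. With culture (the arrays of a mouse and site) as a random block the counts were the same 65 and 78. The correlation within a culture was estimated at 0.0041, so this fit nearly repeats the reported one and is no separate check. Replicate numbers did not pair the samples (correlations of deviations from -0.21 to 0.33), and a replicate block gave 62 rises and 79 falls over both mice, 111 in mouse 1, 116 in mouse 2 and 0 for the difference between mice. Leaving out single arrays gave 98 to 116 in mouse 1, 87 to 122 in mouse 2, 0 to 2 for the difference between mice, 79 to 101 miRNAs shared by the mice and 7.29 to 7.44 for miR-374a, which stayed between 6.47 and 7.40 in the other alternatives. A mouse and site left with 1 array is assumed there to vary like the others. Calls moved by over 1.5 times in mouse 1 with normexp (75), for the difference between mice with quantile normalization (2), normexp (3) and a floor at a lower level (1), and for list tests with an estimated correlation (0) and with fry (11, which does not compare a list with other miRNAs). For the other 64 named miRNAs, 1632 of 1710 values kept direction and call, 63 lost the call in 18 miRNAs (miR-494 in 13 settings, let-7f-1* in 9, miR-575 in 8), 4 gained it (hsa-miR-223 in 2 settings, hsa-miR-513b and hsa-miR-513c without an array) and 11 changed sign in 10 miRNAs. The sign changed with normexp for hsa-miR-218 (0.0298), hsa-miR-95 (0.0541), hsa-miR-24-1* (0.0074), hsa-miR-34a* (0.0441), hsa-miR-200a* (0.12), hsa-miR-205 (0.0059), hsa-miR-23b* (0.10), hsa-miR-9 (0.11) and hsa-miR-126 (0.0759), dim miRNAs with signals below the added offset of 50. It changed for hsa-miR-720 with quantile normalization (-0.47) and in the deposited value table (-0.0874), and the cause was not tested. Of the calls, 35 changed sign in some scaling, 6 of them with a change over 2-fold. The outlier-flagged spots, kept as an alternative chosen after seeing the data, gave 63 rises and 78 falls. For miRNAs near background, signal over background limits the size of a change to a bound.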

Other observations

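All tests in this part were chosen only after the result was seen, as were the miRNAs not already named above. List counts given here repeat planned ones. Outside the lists, miR-375, a miRNA of endocrine and epithelial cells, fell from 320 to 130 signal units, a log2 difference of -1.06 ± 0.05, with values of -1.30 to -0.83 across scalings. Arms of a hairpin had the same sign in 75% of 44 pairs. miR-342-3p and miR-342-5p rose by 0.56 ± 0.07 and 0.59 ± 0.08, miR-361-5p and miR-361-3p by 0.73 ± 0.07 and 0.84 ± 0.17, and miR-140-5p and miR-140-3p fell by 0.72 ± 0.08 and 0.31 ± 0.06. In other pairs the signs differed without both arms passing, as for let-7b* (0.34, not passed) and let-7b (-0.75). On the X chromosome cluster that holds miR-424 and miR-503, miR-450a (-0.77 ± 0.12) fell as well.

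Neighbouring miRNAs had similar site differences: over 110 pairs within 10 kb of each other, 85.5% had the same sign and the median gap was 0.24 on the log2 scale, against 0.56 with values permuted over 217 miRNAs that have a single gene. The permutation p over 10000 draws was 0.0001, the smallest they can give. Whether cross-hybridisation between similar neighbours is the whole cause was not settled. The 40 pairs without miRNAs of related families had a median gap of 0.33 (permutation p = 0.02). The 11 of these that also share no list gave 0.29 (permutation p = 0.09), and relatedness was judged by family without probe sequences. Many of the 40 pairs repeat clusters whose related members can share signal. The permutations, those over the 110 pairs included, treat all miRNAs as exchangeable, so their p-values can be too small. The values are consistent with shared regulation of miRNAs encoded close together, as a hypothesis, and pairs that share a miRNA are not independent.

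Between the mice at the same site 2 miRNAs passed in limma, miR-324-3p, higher in mouse 2 by 0.60, and miR-148b, higher by 0.31, and mouse and slide coincide. Over the 203 miRNAs detected on every array, the spread between mice at a site exceeded that between replicates (median F of 1.81). Simulated noise, independent between miRNAs, gave a median F of 0.83. Array noise shared between miRNAs can move the median F further than this simulation allows, so these values do not establish a spread between mice. Of the 4 arms of miR-221 and miR-222 0 were tested, and 12 of 15 melanocyte and Xq27 miRNAs were detected on no array, while all 10 miR-200 and miR-205 members were tested, in a line that genotyping placed in the melanoma lineage.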
